A study of Mus musculus with 9 samples.

How the data were processed

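RNA was measured in 9 sequencing libraries of group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that make type 2 cytokines, from 10-week-old C57BL/6 mice. Per the labels, the cells were sorted as live, CD45-positive, lineage-negative cells carrying ST2 (the IL-33 receptor, encoded by Il1rl1) and Thy1. The 3 groups of 3 libraries were brain meninges of uninjured mice, brain meninges of mice killed 24 h after a spinal cord contusion of 80 kdyn, and lung of uninjured mice. Per the labels, RNA was taken with the PicoPure kit and amplified with the Ovation RNA-Seq System before library preparation. The labels state that 5 mice were pooled per group and leave open whether each library came from its own pool, so p-values measure the spread between these libraries, which may be technical.

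The deposited values are raw read counts per gene, whole numbers without normalization. Per the submitters' processing notes, FastQC, STAR, HTSeq and the mm9 build were used, with no versions given and no role stated for each. The deposited table holds 23466 genes by Ensembl identifier, and some identifiers are of a kind issued after that build, so no coordinates are given. The table gave a symbol for 15969 genes, 7407 more were named through a reference list matched on the identifier, and 90 kept the identifier alone. In all, 23355 identifiers matched the reference. Gene types came from GENCODE M21 by identifier. The lowest total over the 9 libraries was 2 counts, so genes without reads were not in the table. Whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and values of near-identical copies such as Hspa1a and Hspa1b are uncertain.

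Library totals ranged from 13407277 to 18253462 counts. In a single library, 3 counts, the limit that a count of 0 allows, corresponded to 0.163 to 0.239 CPM (CPM being counts scaled to a common library size, after adjustment by the trimmed mean of M values). This limit covers counting error only, because amplified reads are not independent molecules. For a gene at 0 in all libraries of a group, the fold is given as at least the ratio of the other group's mean to the mean limit of 3 counts per library. No pair of libraries agreed within sampling noise, since the lowest chi-square per degree of freedom over genes was 62.8.

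Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filterByExpr function with the group as argument, which left 15117 genes, and library sizes were scaled by the trimmed mean of M values. All 9 libraries entered 1 fit with a mean per group, because each group had 3 libraries and the spread was estimated over all of them. Robust quasi-likelihood F tests compared injured with uninjured meninges and uninjured meninges with uninjured lung. Genes at a Benjamini-Hochberg adjusted p under 0.05 are called changed. Log2 fold changes are given with a standard error obtained as the fold change divided by the square root of F, and group levels are given as mean CPM ± SD over 3 libraries. The common biological coefficient of variation was 0.91. The median standard error was 0.95 on the log2 scale for the injury comparison, 0.27 for genes above 100 CPM and 1.77 for genes under 10 CPM, so small changes of scarce transcripts were not detectable at this depth and replication.

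Fixed lists, 20 of cell programs and 15 of markers of other cell types, were written before the data were examined. Lists with at least 5 measured members were tested with camera (limma 3.58.1) against all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists tested. Camera with an estimated correlation and fry were alternatives. Counts of changed members are also given adjusted over the list alone.

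The genes named were chosen by a rule written before the data were examined. It takes, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall whose groups did not overlap and whose higher group had at least 10 CPM in each library. Ribosomal, small and predicted RNAs and antigen receptor segments were left out. It adds up to 4 members with the smallest p of each program list and 18 fixed genes whatever their value. It also adds the most abundant member and the member with the smallest p of each list of other cells. Fewer than the rule gives are named, and a gene outside it is said to be so.

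The procedure was tested on simulated counts with 200 changed genes. These were drawn only from genes with a mean of at least 10 CPM, so the shares recovered do not cover scarcer genes. For injured against uninjured meninges, 2% of genes changed 2-fold, 44% of those changed 4-fold, 68% of those changed 8-fold and 70% of those changed 16-fold were recovered among 14412 genes, with 3 false calls among 95. Above 100 CPM, 0%, 90.9%, 100% and 100% of 4, 11, 11 and 8 such genes were recovered. For meninges against lung, 4%, 44%, 74% and 74% were recovered among 14431 genes, with 4 false calls among 103. Above 100 CPM, 22.2%, 100%, 100% and 100% of 9, 7, 13 and 11 such genes were recovered.

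Alternatives were other scaling factors (RLE, upper quartile, library size only), no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0 and limma-voom with and without quality weights. Further alternatives were the 6 libraries compared alone, the replicate number as a block, removal of mitochondrial, hemoglobin and ribosomal RNA genes, a test against a log2 fold change of 1, injured in place of uninjured meninges against lung, and leaving out each library in turn.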

Results

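The libraries held 18253462, 14386843 and 14456879 counts for uninjured meninges, 16730395, 13407277 and 15452799 for injured meninges, and 15731603, 15178366 and 15979968 for lung. Between 13465 genes, in injured meninges 2, and 18452 genes, in uninjured meninges 1, had at least 1 count. Mitochondrial ribosomal RNA took 23.5% to 32.5% of the counts. Spearman correlations across genes, which are not independent replicates, had a median of 0.858 between libraries of a group and 0.81 between libraries of different groups. Injured meninges 2 stood apart, with correlations of 0.795 and 0.799 to the other libraries of its group. On the first principal component (27.8% of the variance) it lay at 203.98, against -110.46 to 47 for the other libraries. Genes of the sort gate were present in all groups. Il1rl1 averaged 2188 ± 337 CPM in uninjured meninges, 2379 ± 400 in injured meninges and 2147 ± 280 in lung (SD, n = 3 each). Ptprc, which encodes CD45, averaged 1526 ± 206, 1820 ± 384 and 1616 ± 271 CPM. Gata3, the transcription factor that ILC2s need, averaged 549 ± 84.2, 536 ± 58.2 and 556 ± 61.3 CPM.

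The first comparison set meningeal ILC2s of mice with spinal cord injury against those of uninjured mice. None of the 3 groups was labelled as sham-operated, so effects of the contusion cannot be told apart from those of the surgery around it. One day after spinal cord contusion, Ikzf3, which encodes the lymphoid transcription factor Aiolos, rose from 273 ± 15.8 to 1906 ± 330 CPM (SD, n = 3 each), a log2 fold change of 2.81 ± 0.19 (SE, edgeR adjusted p = 1.6e-06). Pdcd1, which encodes the inhibitory receptor PD-1, rose from 1.48 ± 0.41 to 65.5 ± 22.2 CPM, a log2 fold change of 5.47 ± 0.64. Neb, known as the gene of a giant muscle protein, rose from 108 ± 45.8 to 999 ± 199 CPM. In the other direction, Stab2, which encodes a scavenger receptor, fell from 830 ± 262 to 176 ± 24.8 CPM, and Thy1, itself a marker of the sort gate, fell from 225 ± 56.3 to 68.0 ± 21.6 CPM, a log2 fold change of -1.73 ± 0.29. In all, 29 of 15117 genes changed, 20 upward and 9 downward, and 1352 had an unadjusted p under 0.05. DESeq2 called 435 genes, 213 upward and 222 downward, without the upward lean. The edgeR test on only the 6 libraries compared called 12 genes, 11 of them among the 29. The groups did not overlap in CPM for 12.1% of genes, against 10% by chance.

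Among other genes that rose, Tnfrsf9, the costimulatory receptor 4-1BB, changed by 5.12 ± 0.87 on the log2 scale (adjusted p = 0.022). Gpr35, an orphan-type G-protein-coupled receptor, rose from 0.13 ± 0.17 to 33.5 ± 15.8 CPM, and Ramp3, a subunit of receptors for adrenomedullin and related peptides, rose from 1.39 ± 1.63 to 34.4 ± 22.2 CPM. Jag1, a Notch ligand, rose from 16.3 ± 11.9 to 191 ± 77.6 CPM. Ifngr1, a chain of the interferon gamma receptor, rose from 94.6 ± 37.7 to 305 ± 68.9 CPM. Raph1 rose from 16.9 ± 14.5 to 184 ± 28.7 CPM. Among genes that fell were Ccr2, a chemokine receptor, from 1368 ± 118 to 607 ± 125 CPM, and Inpp4b, a lipid phosphatase, from 1986 ± 105 to 957 ± 85.4 CPM. Flrt2 fell from 163 ± 13.4 to 41.5 ± 11.2 CPM and Myo6 from 184 ± 38.2 to 49.3 ± 12.7 CPM. Nfkbid, an NF-kB regulator, fell from 34.8 ± 12.1 to 6.99 ± 3.73 CPM. Ighm, an immunoglobulin gene outside the naming rule and chosen after its values were seen, fell from 579 ± 359 to 45.0 ± 15.3 CPM. The B cell marker Ebf1 had 16.6 ± 6.2 against 2.94 ± 3.35 CPM and was not called (edgeR adjusted p = 0.52). Of 9 measured B cell markers, 5 had a positive and 4 a negative log2 fold change. Whether RNA of B cells contributed to the level of Ighm was not tested.

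**Figure D1:**
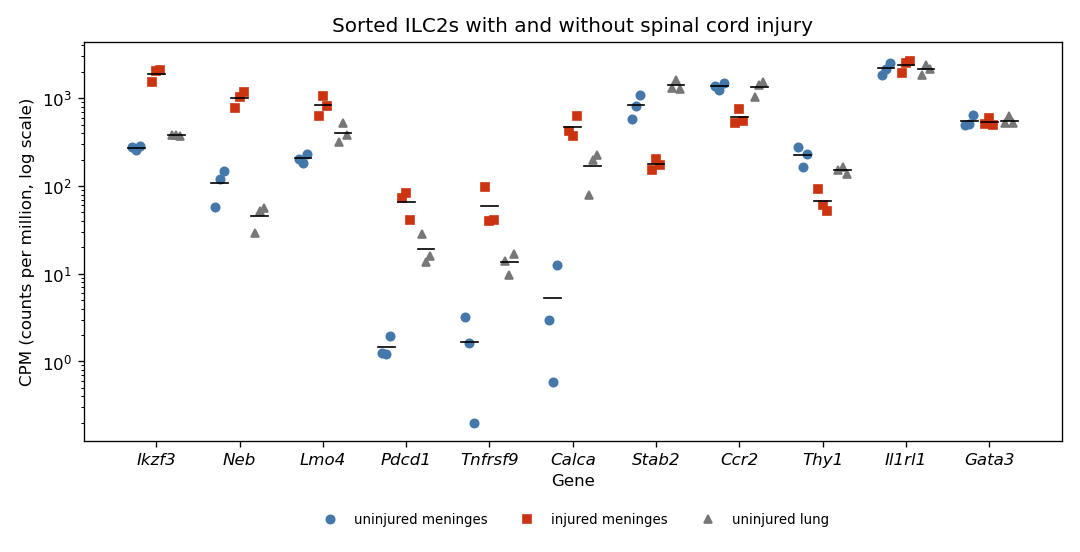
CPM of 11 genes (log axis) in each of the 9 libraries, with blue circles for uninjured meninges, red squares for injured meninges, grey triangles for uninjured lung and a black bar at each group mean. Ikzf3 lies between 255 and 285 CPM in uninjured and between 1527 and 2125 CPM in injured meninges, while the groups overlap for Il1rl1 and Gata3.

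Calca, which encodes calcitonin gene-related peptide, stood at 5.33 ± 6.26 CPM in uninjured and 473 ± 134 CPM in injured meninges without passing the test (log2 fold change 6.48 ± 1.05, adjusted p = 0.085), and was called in 6 of 21 alternatives, among them without uninjured meninges 2 (adjusted p = 0.0034) and without uninjured meninges 3 (0.000887). Plaur, with 1.01 ± 1.53 against 50.3 ± 14.2 CPM (adjusted p = 0.072), and Il18r1, with 20.1 ± 11.5 against 92.2 ± 24.1 CPM (adjusted p = 0.085), also missed the threshold. So did Tnfaip3 (1.36 ± 0.28, adjusted p = 0.074), Nr4a3 (1.96 ± 0.42, adjusted p = 0.086) and Rora (1.04 ± 0.21, adjusted p = 0.075). Plaur, Il18r1, Tnfaip3 and Rora were each called in 4 of 21 alternatives and Nr4a3 in 3. Among these were the fits without uninjured meninges 1 for Plaur (adjusted p = 0.0066) and Il18r1 (0.044), without injured meninges 2 for Tnfaip3 (0.0087), without injured meninges 1 for Rora (0.024) and without lung 1 for Nr4a3 (0.049). None of the 12 measured members of the type 2 cytokine list was called over all genes, and 1, Calca, rose when adjusted over the list alone. Il5 averaged 10.4 ± 11.9 CPM in uninjured and 17.8 ± 10.6 CPM in injured meninges. Il13 averaged 6.96 ± 4.29 and 5.79 ± 3.44, and Il4 averaged 6.32 ± 3.42 and 8.10 ± 5.47. Csf2 averaged 11.1 ± 10.6 and 8.78 ± 7.06, and Areg averaged 19.1 ± 7.19 and 8.69 ± 5.11. The list had a median log2 fold change of -0.30 and a mean of 0.25, so their signs differ, and its camera adjusted p was 0.74.

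With camera, 5 of 31 lists were called. Of the 10 splits of these 6 libraries into 3 and 3, the real one included, 5 called as many lists. The number of lists called therefore does not set the real grouping apart from others. Alarmin and cytokine receptors moved upward (adjusted p = 2.9e-05; adjusted p = 0.061 with an estimated correlation), with 2 of 26 measured members called, Tnfrsf9 and Ifngr1. When adjusted over the list alone, 6 rose. The interferon gamma response moved downward (adjusted p = 2.9e-05; adjusted p = 0.058 with an estimated correlation). None of its 20 members was called over all genes, and 3 fell when adjusted over the list alone. Psmb9, a proteasome subunit, had 27.2 ± 4.89 against 3.69 ± 0.48 CPM (adjusted p = 0.18). Gbp6 had 21.6 ± 7.88 against 2.82 ± 0.58 CPM (adjusted p = 0.27). Cxcl10 had 4.22 ± 4.69 CPM against 0 in all 3 injured libraries, at least 20.9-fold lower, or at least 7.50-fold without uninjured meninges 1 (adjusted p = 0.097). ILC2 identity genes moved upward (adjusted p = 0.0046; adjusted p = 0.41 with an estimated correlation). Lmo4 rose from 207 ± 22.7 to 829 ± 219 CPM, and Thy1 fell. Over all genes 20 of 22 members did not pass, or 17 when adjusted over the list alone. Il7r had 1301 ± 224 against 2086 ± 367 CPM (adjusted p = 0.22). None of the following was called: Klrg1 27.3 ± 12.8 against 37.7 ± 8.51, Il17rb 397 ± 135 against 255 ± 59.4 and Arg1 167 ± 27.9 against 99.9 ± 49.95. Glucocorticoid response genes moved upward (adjusted p = 0.041; adjusted p = 0.45 with an estimated correlation). The list was called in 11 of 19 alternatives (adjusted p 0.0078 to 0.48), and not without uninjured meninges 3 (0.27), injured meninges 1 (0.051) or injured meninges 3 (0.19). No member was called over all genes, and 2 rose when adjusted over the list alone. Irs2 stood at 64.0 ± 7.84 against 155 ± 20.4 CPM, Fkbp5 at 78.5 ± 11.5 against 98.7 ± 3.19 and Tsc22d3 at 25.5 ± 17.9 against 32.1 ± 10.1. Mki67, a marker of cell division, had 24.8 ± 4.44 against 13.8 ± 7.77 CPM (adjusted p = 0.76).

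Among lists of other cell types, fibroblast markers moved downward (camera adjusted p = 0.048; adjusted p = 0.76 with an estimated correlation). No member was called over all genes, and 2 fell when adjusted over the list alone. The list was called in 6 of 19 alternatives (adjusted p 0.00053 to 0.94). The call was lost without uninjured meninges 1 (adjusted p = 0.94), injured meninges 2 (0.13) or injured meninges 3 (0.42), and without lung 1 (0.063), lung 2 (0.058) or lung 3 (0.062). Pdgfra had 2.88, 0.65 and 0.07 CPM in uninjured meninges and 0 in the injured libraries and missed the threshold (adjusted p = 0.14; 0.045 without uninjured meninges 3). It was at least 5.94-fold lower, or at least 1.76-fold without uninjured meninges 1. Monocyte and macrophage markers had a positive log2 fold change for 12 of 13 members, with a median of 0.91, and were not called (adjusted p = 0.053; adjusted p = 0.76 with an estimated correlation). Cd68 had 1.25, 1.16 and 1.14 CPM in uninjured and 5.56, 30.4 and 4.70 CPM in injured meninges (adjusted p = 0.46), and Lyz2 averaged 20.2 ± 19.1 against 29.7 ± 36.5 CPM. The 5 list calls were lost with an estimated correlation, and fry called 2 lists. The count of called genes was 18 without injured meninges 2, the library that stood apart and had the fewest detected genes, and 19 without uninjured meninges 2. The calls of Ikzf3, Neb, Pdcd1, Lmo4, Stab2, Flrt2 and Inpp4b held in all 9 fits with 1 library left out, those of Thy1 and Ccr2 in 5, Jag1 in 4, Ramp3 in 3 and Nfkbid in 2.

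The second comparison set ILC2s of uninjured meninges against those of uninjured lung. Immediate early and NF-kB target genes, which cells induce rapidly on stimulation, were lower in meninges as lists. Nr4a3, a nuclear receptor, averaged 18.5 ± 9.76 CPM in meninges and 952 ± 393 CPM in lung (SD, n = 3 each), a log2 fold change of -5.69 ± 0.49 (SE, edgeR adjusted p = 4.5e-05). Tnfaip3, which encodes the NF-kB inhibitor A20, averaged 148 ± 31.4 and 1776 ± 259 CPM, a log2 fold change of -3.59 ± 0.30. Areg, the gene of the growth factor amphiregulin, averaged 19.1 ± 7.19 and 203 ± 127 CPM. Higher in meninges were Ms4a6b, at 76.9 ± 28.4 against 7.19 ± 6.55 CPM, and Kbtbd11, at 429 ± 31.2 against 171 ± 63.4. Also higher were St3gal6, a sialyltransferase gene, at 371 ± 19.6 against 163 ± 6.08, and Myo6, at 184 ± 38.2 against 65.7 ± 9.34. In all, 96 of 15117 genes differed, 6 higher and 90 lower in meninges, and 1207 had an unadjusted p under 0.05. The groups did not overlap in CPM for 18.2% of genes, against 10% by chance.

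Of 25 immediate early genes, 5 were called lower over all genes, and 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.4e-21; adjusted p = 0.034 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, averaged 27.8 ± 13.3 CPM in meninges and 304 ± 71.9 in lung. Zfp36, an RNA-binding protein that promotes the decay of cytokine messages, averaged 118 ± 85.9 and 808 ± 238. Atf3 was at 0 in all 3 uninjured meningeal libraries and at 41.2 ± 13.2 CPM in lung, at least 221-fold lower. Of 20 NF-kB targets, 4 were called lower, Tnfaip3, Nfkbia, Rel and Nfkbid, and 9 when adjusted over the list alone (camera adjusted p = 1.6e-14; adjusted p = 0.028 with an estimated correlation). Nfkbia averaged 28.2 ± 6.38 against 224 ± 107 CPM, Rel 59.3 ± 16.7 against 288 ± 107 and Nfkbid 34.8 ± 12.1 against 168 ± 47.7. Of 19 heat shock and unfolded protein genes, 3 were called lower and 8 when adjusted over the list alone (camera adjusted p = 2.8e-07, or 0.076 with an estimated correlation). Hsp90aa1 stood at 90.3 ± 14.4 against 400 ± 204 CPM and Hspa1b at 1.75 ± 1.56 against 44.9 ± 28.6. Hspa1a was at 0 in meninges and 47.3 ± 39.9 in lung, at least 254-fold lower, or at least 162-fold without lung 3. Its call was lost without any 1 of the uninjured meningeal libraries (adjusted p = 0.12, 0.17 and 0.16), without lung 2 (0.10) and without lung 3 (0.13). In the same comparison the list of lung epithelial markers was called (adjusted p = 2.1e-14).

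**Figure D2:**
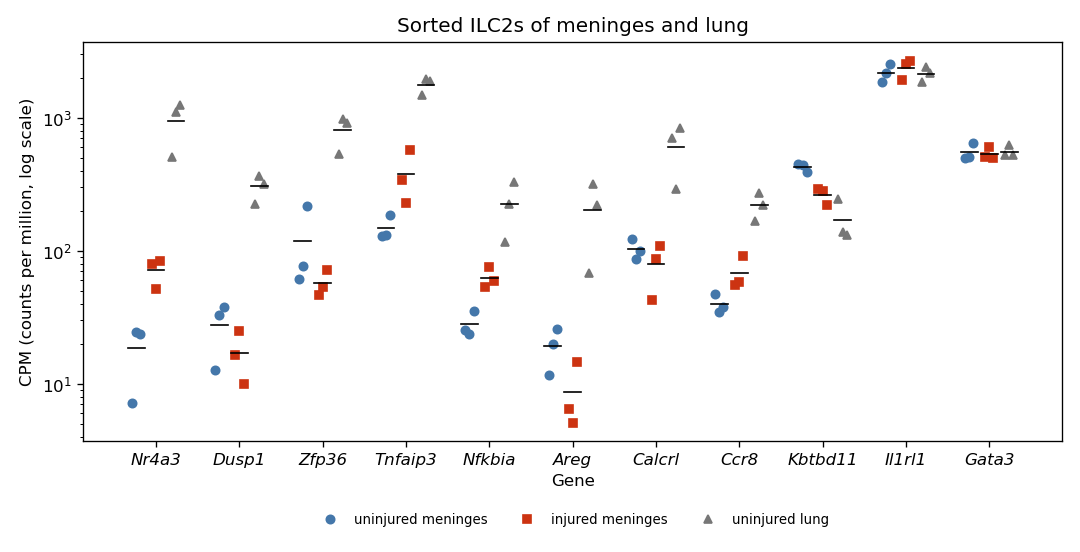
CPM of 11 genes (log axis) in each of the 9 libraries, with blue circles for uninjured meninges, red squares for injured meninges, grey triangles for uninjured lung and a black bar at each group mean. Tnfaip3 lies between 129 and 184 CPM in uninjured meninges and between 1479 and 1952 CPM in lung, while the groups overlap for Il1rl1 and Gata3.

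Marker lists of other cell types differed between the tissues. All 7 measured lung epithelial markers had a negative log2 fold change, 2 were called and 6 passed when adjusted over the list alone (camera adjusted p = 2.1e-14; adjusted p = 0.034 with an estimated correlation). Their median was -11.22, or -8.18 with genes at 0 set to their bound. Sftpa1, a surfactant protein gene, had 266, 11.3 and 216 CPM in the 3 lung libraries and a mean of 0.059 ± 0.055 CPM in meninges. Scgb1a1, a club cell gene, averaged 910 ± 473 CPM in lung (adjusted p = 0.13; 0.029 without injured meninges 3). Fibroblast markers were lower in meninges as a list (adjusted p = 9.2e-06; adjusted p = 0.13 with an estimated correlation), with 0 of 11 called over all genes and 1 when adjusted over the list alone. Endothelial markers were lower as well (adjusted p = 8.4e-05; adjusted p = 0.22 with an estimated correlation), with 0 of 10 called and 3 when adjusted over the list alone. Neural and glial markers were higher (adjusted p = 0.017; adjusted p = 0.13 with an estimated correlation), with 0 of 5 called either way. This list was called in 13 of 17 alternatives, and not without uninjured meninges 1 (adjusted p = 0.22) or lung 2 (0.053). Several genes at 0 in meninges had moderate levels in lung. Tmem100, with 62.2, 24.0 and 107 CPM in the 3 lung libraries and so lowest in lung 2 like Sftpa1, was at least 346-fold lower in meninges, Inmt at least 251-fold and Bmp3 at least 150-fold. Pcolce2 was at least 121-fold lower, Dpt at least 96.6-fold and Zfp697 at least 81.2-fold. These genes did not all share the pattern of Tmem100 over the lung libraries. Inmt was highest in lung 2, with 34.5, 69.1 and 36.8 CPM. Dpt was lowest there, with 13.7, 12.7 and 27.5 CPM, while Bmp3, Pcolce2 and Zfp697 were not.

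Several receptor genes were lower in meninges. They included Calcrl, the receptor subunit that binds calcitonin gene-related peptide with a RAMP partner, at 103 ± 17.3 against 608 ± 280 CPM, and Ramp3, at 1.39 ± 1.63 against 58.4 ± 19.1. Calcrl had 699, 294 and 830.4 CPM in the 3 lung libraries, lowest in lung 2. The endothelial markers Pecam1, with 194, 78.3 and 140.2 CPM, and Cdh5, with 165, 41.2 and 107 CPM, were lowest in that library as well, and so was Sftpa1, with 266, 11.3 and 216 CPM. Pdcd1 averaged 1.48 ± 0.41 against 19.4 ± 8.13 CPM and Ccr8 averaged 39.9 ± 6.89 against 220 ± 52.5. Cd44 averaged 290 ± 20.3 against 721 ± 173 CPM and Kit averaged 249 ± 50.9 against 721 ± 121. Rgs2, a regulator of G-protein signalling, averaged 227 ± 106 against 1335 ± 411 CPM. The program lists these genes stand in were called lower in meninges, while Kit stands in the untested list of mast cells and basophils. For neuropeptide and lipid mediator receptors (adjusted p = 0.010; adjusted p = 0.076 with an estimated correlation), 2 of 26 members were called, and 5 were lower and 1 higher when adjusted over the list alone. Its call was lost without uninjured meninges 2 (adjusted p = 0.054). For chemokine receptors and trafficking (adjusted p = 0.0093; adjusted p = 0.13 with an estimated correlation), 2 of 24 were called, and 6 were lower and 2 higher when adjusted over the list alone. Its call was lost without lung 3 (adjusted p = 0.052). For checkpoint and inhibitory receptors (adjusted p = 0.024; adjusted p = 0.10 with an estimated correlation), 1 of 16 was called, also when adjusted over the list alone. This list was called in 14 of 19 alternatives, and not without uninjured meninges 1 (adjusted p = 0.12), uninjured meninges 2 (0.067) or lung 3 (0.092). For TGF-beta and tissue residency (adjusted p = 0.0021; adjusted p = 0.062 with an estimated correlation), 1 of 18 was called, and 5 were lower and 1 higher when adjusted over the list alone. Alarmin and cytokine receptors were lower as a list (adjusted p = 0.0032; adjusted p = 0.076 with an estimated correlation). None of 26 was called over all genes, and 2 were lower and 1 higher when adjusted over the list alone.

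Of 12 type 2 effector cytokine genes, Areg was called lower and 6 passed when adjusted over the list alone (camera adjusted p = 6.8e-07; adjusted p = 0.051 with an estimated correlation). Calca stood at 5.33 ± 6.26 CPM in meninges and 169 ± 79.3 in lung (adjusted p = 0.092, with 0.0097 without uninjured meninges 2 and 0.00091 without uninjured meninges 3). Csf2 stood at 11.1 ± 10.6 against 70.6 ± 51.2. Il5 stood at 10.4 ± 11.9 against 47.8 ± 41.1, Il13 at 6.96 ± 4.29 against 10.7 ± 3.68 and Il4 at 6.32 ± 3.42 against 0.69 ± 0.71 CPM, and none of these 5 was called. Wound repair and matrix genes were lower (camera adjusted p = 6.7e-10, or 0.034 with an estimated correlation), with 1 of 21 called and 7 when adjusted over the list alone. The fibroblast and endothelial marker lists were lower as well, with median log2 fold changes of -2.65 and -1.5. Whether RNA of such cells contributed was not tested. Glucocorticoid response genes were lower (adjusted p = 0.0042; adjusted p = 0.13 with an estimated correlation), with 1 of 19 called, and 2 lower and 1 higher when adjusted over the list alone. Their call was lost without uninjured meninges 3 (adjusted p = 0.062). Irs2 averaged 64.0 ± 7.84 against 389 ± 154 CPM. Lipid metabolism genes were lower (adjusted p = 0.010; adjusted p = 0.13 with an estimated correlation), with 2 of 22 called and 4 when adjusted over the list alone. Dgat1 stood at 29.9 ± 8.87 against 200.4 ± 116 CPM and Cd36 at 1.77 ± 1.48 against 211 ± 128. Cd36 had 245, 69.2 and 318 CPM in the 3 lung libraries, lowest in lung 2, as were Pecam1, Cdh5 and Sftpa1. Class II antigen presentation genes were lower as a list (adjusted p = 0.00015; adjusted p = 0.13 with an estimated correlation), with 0 of 10 called either way.

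Interferon gamma response genes were higher in meninges (camera adjusted p = 4.0e-05; adjusted p = 0.034 with an estimated correlation), with none of 20 called over all genes and 6 higher when adjusted over the list alone. Irgm1 averaged 67.2 ± 11.5 against 24.5 ± 7.53 CPM and Tap1 75.6 ± 28.3 against 26.7 ± 10.2. Type I interferon response genes were higher as well (adjusted p = 0.0093; adjusted p = 0.076 with an estimated correlation), with 0 of 23 called either way. Among ILC2 identity genes no member was called over all genes, and 1 was higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.12). Il17rb, the IL-25 receptor, had 397 ± 135 against 152 ± 46.3 CPM (adjusted p = 0.0501). Rora had 486 ± 18.01 against 952 ± 215 (adjusted p = 0.053) and Lmo4 207 ± 22.7 against 405 ± 106 (adjusted p = 0.095). Il17rb was called in 14 of 21 alternatives (adjusted p 0.0019 to 0.90), Rora in 13 (0.0036 to 1) and Lmo4 in 5 (0.016 to 1). With 1 library left out, Il17rb was called without uninjured meninges 1 (adjusted p = 0.014), injured meninges 1 (0.048), 2 (0.019) or 3 (0.047), or lung 2 (0.046). Rora was called without injured meninges 1 (0.018), 2 (0.032) or 3 (0.035) or lung 1 (0.035), and Lmo4 without injured meninges 1 (0.045) or 2 (0.038). Klrg1 averaged 27.3 ± 12.8 against 70.1 ± 13.2, Thy1 225 ± 56.3 against 152 ± 13.97 and Arg1 167 ± 27.9 against 199 ± 81.5.

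With camera, 19 of 31 lists were called, 3 higher and 16 lower in meninges, and 5 of them held with an estimated correlation. The count of called genes was 51 without lung 3, 53 without uninjured meninges 2, 196 without injured meninges 2 and 536 with DESeq2, 99 of them higher and 437 lower in meninges. With 1 library left out, the calls of Nr4a3, Tnfaip3, Dusp1, Zfp36, Nfkbia, Areg, Calcrl, Ramp3, Pdcd1 and Ccr8 held in all 9 fits, those of Ms4a6b and Kbtbd11 in 5, Myo6 and Hspa1a in 4, and St3gal6, Dpt and Zfp697 in 3.

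Genes called in both comparisons numbered 6. Pdcd1, Ramp3 and Raph1 rose after injury and were lower in uninjured meninges than in lung, where 0.119 genes would be shared by independent lists. Nfkbid and Hpgd, the latter outside the naming rule and chosen after its values were seen, fell after injury and were lower in uninjured meninges than in lung (0.054 by independent lists), and Myo6 fell after injury and was higher in uninjured meninges (0.004). Hpgd had 148, 41.2 and 186 CPM in the 3 lung libraries, lowest in lung 2, as were Pecam1, Cdh5 and Sftpa1. Both comparisons use the uninjured meningeal libraries. In 30 simulations of unchanged groups against them the most shared genes was 0, but no simulated comparison called more than 2 genes, so this value gives no level to hold the 6 against. With 3 such libraries no split leaves 2 in each part, and part of the overlap may come from the shared libraries. The interferon gamma, alarmin and cytokine receptor, and glucocorticoid response lists were called in both comparisons with opposite signs. Deviations of the shared libraries would also give such signs, and whether they did was not tested. The fibroblast list was called with a negative direction in both comparisons.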

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

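All alternatives were planned before the data were examined. No other scaling moved the median of all genes by over 0.098 on the log2 scale. For genes changed after injury (29), other settings gave 78 with no filter on low counts, 435 with DESeq2, 17 with limma-voom, 12 with only the 6 libraries compared and 5 against a log2 fold change of 1, where the stricter null makes fewer calls by construction. Leaving out 1 library gave 18 (without injured meninges 2) to 27. DESeq2 called all 29 of the genes and limma-voom 17 of them. For genes that differed between uninjured meninges and lung (96), the counts were 193 with no filter, 536 with DESeq2, 195 with limma-voom, 329 with quality weights, 226 with only the 6 libraries, 41 against a log2 fold change of 1, 159 with injured in place of uninjured meninges, and 51 (without lung 3) to 196 (without injured meninges 2) with 1 library left out. For lists after injury (5), the counts were 3 with the 5 CPM filter, 3 with only the 6 libraries, 0 with an estimated correlation, 2 with fry, and 4 to 8 (without uninjured meninges 2) with 1 library left out. For lists between meninges and lung (19), they were 10 with injured in place of uninjured meninges, 5 with an estimated correlation, 12 with fry, and 18 to 20 with 1 library left out. The injured libraries are in neither group of the comparison of meninges with lung. Leaving out injured meninges 2 can therefore move its 96 genes to 196 only through the shared spread, scaling or filter. Which of these did so was not tested, nor was the cause for the other counts.

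The replicate numbers showed no clear pairing of the libraries, which does not exclude a weak one. After removal of group means, same-numbered libraries correlated between -0.024 and 0.119 and other pairs between -0.149 and 0.122. Of 9 same-numbered pairs, 1 was over 0.1, and in 8 of 18 cases a library matched best with its own number. With the replicate number as a block, 43 genes were called after injury and 136 between meninges and lung, with 4 and 19 lists. Under the block the log2 fold change after injury was -0.34 for Il4 and 0.037 for Csf2, both turned in sign.

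With injured in place of uninjured meninges against lung, the log2 fold change became 1.49 for Calca, 1.76 for Pdcd1, -0.41 for Myo6, 0.071 for Rora, 1.03 for Lmo4, 0.752 for Raph1, 0.17 for Ptprc and -1.16 for Thy1, and the interferon gamma response (adjusted p = 0.996) and alarmin and cytokine receptor lists (adjusted p = 0.261) turned direction without being called. Between meninges and lung, Gata3 turned to 0.024 with upper-quartile factors and 0.088 with library size only, Ptprc to 0.029 with library size only, and Il1rl1 to -0.001 with RLE factors and -0.002 with DESeq2. After injury, Csf2 turned to 0.289 with quality weights. Leaving out 1 library gave, after injury, -0.771 to 0.199 for Il13, -0.204 to 0.79 for Il4, -1.208 to 0.801 for Csf2, -0.126 to 0.097 for Gata3, -0.11 to 0.941 for Tsc22d3 and -1.235 to 1.606 for Lyz2, and between meninges and lung -0.149 to 0.056 for Gata3, -0.091 to 0.128 for Il1rl1, -0.184 to 0.034 for Ptprc and -0.432 to 0.109 for Arg1. The cause was not tested. After injury, the calls of Tnfrsf9, Gpr35, Raph1 and Ighm held in 7 of 9 fits with 1 library left out, Ifngr1 and Myo6 in 6 and Hpgd in 3. Between meninges and lung, Bmp3 held in 8, Rel, Cd44 and Pcolce2 in 7, Cd36 in 6, Nfkbid, Hspa1b and Raph1 in 5 and Hpgd in 3. Over the named genes and alternatives, 205 values fell short of a threshold passed before and 82 passed one missed before; 63 list values fell short. DESeq2 gave no adjusted p for 8280 genes, which stayed out of these counts.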

Other observations

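The tests of the Thy1 pattern and of tissue handling were chosen only after the results were seen. Neutrophil markers had a median log2 fold change of 2.61 between uninjured meninges and lung without passing camera (adjusted p = 0.095). T cell markers (adjusted p = 0.19), B cell markers (0.28), natural killer cell and ILC1 markers (0.45), monocyte and macrophage markers (0.20) and dendritic cell markers (0.21) were not called there. Nor were red blood cell markers (0.71), proliferation genes (0.34), glycolysis and hypoxia genes (0.43), nuclear genes of oxidative phosphorylation (0.28) and p53 and apoptosis genes (0.45). After injury the camera adjusted p was 0.67 for immediate early genes, 0.87 for NF-kB targets, 0.12 for the type I interferon response, 0.95 for proliferation and 0.21 for heat shock. It was 0.15 for glycolysis and hypoxia, 0.39 for lipid metabolism, 0.84 for oxidative phosphorylation and 0.74 for chemokine receptors. It was 0.79 for neuropeptide and lipid mediator receptors, 0.12 for checkpoint receptors and 0.57 for TGF-beta and residency. It was 0.22 for p53 and apoptosis, 0.84 for class II antigen presentation and 0.40 for wound repair. For other cells it was 0.42 for T cells, 0.12 for B cells, 0.48 for natural killer cells and ILC1 and 0.86 for neutrophils. It was 0.74 for dendritic cells, 0.39 for endothelial cells, 0.43 for lung epithelium, 0.50 for neural and glial cells and 0.79 for red blood cells. The ILC3, mast cell and basophil, eosinophil and platelet lists had 2, 4, 1 and 1 measured members and were not tested.

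Thy1 fell after injury by 1.73 on the log2 scale, beside 0.12 ± 0.17 for Il1rl1 and -0.04 ± 0.19 for Gata3. Dilution by cells other than ILC2s would lower the other identity genes alike. The 21 others had a median of 0.38 (95% bootstrap interval 0.12 to 0.53, over genes and not over libraries). These values argue against dilution as the whole cause. They are no independent test, because the list had been seen to move upward before the test was chosen, and the interval does not measure the spread between libraries. A sort that kept cells of lower Thy1 from injured animals cannot be told apart from a lower level in the animals, because both predict the value of -1.73 and sort and injury coincide in every library. A change with injury itself remains untested.

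Immediate early and NF-kB genes, 45 together, had a median log2 fold change of -1.57 between uninjured meninges and lung. RNA of lung epithelial cells may contribute, and with the epithelial marker level of each library as a covariate the median became -4.39. That met the bound set beforehand against this explanation, but the test was judged void after the result was seen, because marker level and tissue nearly coincide and the epithelial list itself went past 0, from -11.22 to 5.94. Lung 2 had the lowest epithelial marker sum of the lung libraries (655 CPM, against 2230 and 1340). It also had the highest summed level of the 45 genes (16254 CPM, against 10251 and 15481). By the median of these genes, lung 3 was highest instead (163 CPM, against 94.8 in lung 1 and 137 in lung 2). The sum and the median thus rank the lung libraries differently, and 1 library excludes nothing. Different dissection and digestion of the tissues cannot be told apart from a difference in the animals, since the 3 lung libraries above every uninjured meningeal library are what both predict. A difference between tissues stays open and untested.

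A hypothesis was that changes after injury follow the difference between lung and uninjured meninges, as for Pdcd1, Ramp3 and Raph1. Over 8111 genes with a mean of at least 10 CPM the covariance of these log2 differences was 0.211 (correlation 0.229, across genes), against 0.245 to 0.295 in 30 simulations of unchanged groups that share the uninjured libraries, and 0.199 from the observed spread of those libraries. The value lies below the simulated range and 0.012 above the other estimate, so it met neither bound set beforehand and gives no evidence of a shared effect across genes.

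Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 29 genes after injury and the highest of the others 0, with 1 of 10 splits as large, and 96 genes between meninges and lung against 0, also 1 of 10. Every other split mixes both groups, so a real difference would widen the spread within its parts and lower its count. The 0 is therefore no chance level for the 29 or the 96. For lists the real split gave 5 after injury and the highest of the others 8, with 5 of 10 splits giving as many, and 19 between meninges and lung against 10, with 1 of 10 as large.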
